A study of Chlamydomonas reinhardtii with 16 samples.

How the data were processed

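RNA-seq had been run on synchronised cultures of the green alga Chlamydomonas reinhardtii, strain CC-5390, at 16 times of one day. Per the labels, cells grew at 28 °C during 12 h of light and at 18 °C during 12 h of darkness. Total RNA was extracted with Trizol, depleted of ribosomal RNA and made into strand-specific Illumina libraries, per the labels' protocols. One library was given per time, with no replicate of any time. P-values of comparisons between groups of times measure the spread within groups, mostly of neighbouring times, and changes with time inside a group count as error. Those of the test for rhythmic genes measure the departure from a smooth daily curve. Neither measures the spread between repeated cultures. Times are given in hours from the moment the light came on, so that −1 h is 1 h before it.

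The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) as deposited by the authors, with a column for each time point and a row for each of 17824 genes. STAR 2.4.0j, SAMtools 1.3 and Cuffdiff 2.0.2 are named in the submitters' processing notes, without the role of each. Whether the authors rescaled libraries against each other, and whether their counting used strand, is not given in the sources used here. Gene models were those of the deposited annotation, which carries build v5.5 for the nucleus and v4.4 for the organelles. The table held 17741 nuclear, 75 chloroplast and 8 mitochondrial genes, of which 17823 were found in that annotation. Each row is counted as a gene here, although exons of psaA and copies of psbA and I-CreI have rows of their own. Gene symbols were the short names in the deposited table, given for 2974 genes (16.7%), so most genes could not be named. The column for 0 h carries the word light in its name, while the sample's label calls it dark; it was assigned by its time and treated as dark.

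FPKM values do not return read counts. Low values showed no steps of whole reads when each other library was compared with that at −11 h. Among genes above 0 and below 0.3 FPKM in both, the fullest bin of their log2 ratio held 0.9 to 1.95%. Depth is therefore unknown, and no counting interval is given. FPKM sums ranged from 618213 at −5 h to 1288975 at 0.5 h, and chloroplast genes took 54.0 to 61.2% of them. A value of 0 means only that a gene is listed at 0, since 8 genes above 20 FPKM in 1 library are listed at 0 in another.

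Samples were grouped into 6 windows before the data were examined, as were the tests, lists, thresholds and most alternatives. Early night held −11, −9 and 13 h, mid night −7, −5 and −3 h, late night −1, −0.5 and 0 h, the first hour of light 0.5 and 1 h, morning 3 and 5 h, and late day 7, 9 and 11 h. The −11 and 13 h samples fall at the same hour of the cycle, a day apart. Values were transformed to log2(FPKM + 1), so that changes of low genes are understated, and genes with a mean of at least 1 FPKM were kept, 11000 of 17824. A linear model of the 6 windows was fitted with limma 3.58.1 in R 4.3.3, with a variance prior that followed expression level. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1. The comparisons from this model, each two-sided, were light against dark (3 windows against 3), dawn (first hour of light minus late night), day (late day minus first hour of light), dusk (early night minus late day) and night (late night minus early night). Rhythmic genes were those passing limma's F test of sine and cosine terms with periods of 24 and 12 h, at a fitted range of at least 1 on the log2 scale.

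Gene lists fixed in advance numbered 22: light-harvesting antenna, photoprotection, nuclear subunits of the photosystems, cytochrome b6f and plastid ATP synthase, chloroplast-encoded photosynthesis genes, chlorophyll and haem biosynthesis, the Calvin-Benson cycle, the carbon-concentrating mechanism, DNA replication, mitosis and cell-cycle regulators, core histones, cilia, cytosolic and plastid ribosomal proteins, the mitochondrial respiratory chain, fermentation and anoxia, starch metabolism, heat shock chaperones, copper, iron and zinc limitation, nitrogen, sulfur and phosphorus limitation, clock and photoreceptors, gamete and zygote markers, and daughter-cell release and cell wall. Lists with at least 5 measured members were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over lists, and again with an estimated correlation and with fry. Fry asks whether the members of a list change, without comparing them with other genes. Where most genes change, a fry call does not set a list apart.

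Genes named in each comparison were chosen by a rule. Among called genes with a symbol and a mean of at least 5 FPKM, and, except for light against dark, with no overlap between the samples of both sides, the rule took the 8 largest rises and the 8 largest falls. It added, for each list with at least 25% of its measured members called, the 2 with the largest change. Chance alone gives no overlap for 10% of genes with 3 samples against 3 and for 20% with 2 against 3, if samples are interchangeable. Neighbouring times resemble each other, so any slow trend can part 2 windows and these shares are too low a baseline here. The share over all genes is not given. Outside light against dark, no overlap was a condition for the largest rises and falls and adds no support to them. In light against dark, where the rule did not ask for it, 19 of 40 named genes had no overlap. List members that went against their list, members making up counts of 5 or fewer, and the genes of the closing observations were named outside the rule, after their values were seen. Positions and exon numbers are those of the deposited annotation. Because the counting of shared reads is unknown, 50-base stretches occurring in more than 1 gene were counted. Of 120 different named genes, 27 shared at least 5% of theirs, and their values are uncertain.

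Alternatives tried were a pseudocount of 0.1 FPKM, no filter, a mean of at least 5 FPKM, median-ratio rescaling, nuclear genes alone scaled to an equal sum, quantile normalization, a variance prior without trend, each library left out in turn, 24 h terms alone, a fit of light against dark samples without windows, no minimum change, a fit of the compared windows alone, 13 h alone as early night and early night without 13 h. A fit without −1 and 1 h together was added after the data were seen.

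The fits were tested on simulated data with 200 of 11000 genes changed. At log2 changes of 1.5 and 4, light against dark recovered 94 and 100% of them with 3 false calls, dawn 72 and 100% with 6, day 80 and 100% with 3, dusk 84 and 100% with 9, night 86 and 96% with 6, and the F test 84 and 100% with 11. Noise was drawn independently for each library, without the resemblance of neighbouring times or trends within windows. The numbers of false calls therefore do not show how well error is controlled in these data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and the data.table package (version 1.17.8) in R, served for joins, checks and plots.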

Results

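Transcript levels were followed through one day and night of Chlamydomonas cultures that divide in step with the light. The 16 libraries comprised 9 from the dark and 7 from the light, each at its own time, and fell into 6 windows of 2 or 3 libraries. Between 8483 genes (1 h) and 10574 genes (11 h) reached 1 FPKM in a library. The −1 and 1 h libraries stood apart from the rest: 62 and 81 genes were listed at 0 in them, against 301 to 851 in the other 14, so dawn is also given within libraries of one kind, and day and night also without these 2.

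The first question was how much of the transcriptome varies over the cycle and when. Of 11000 genes, 8129 (73.9%) were rhythmic by limma's F test, with a median fitted range of 2.04 on the log2 scale, and 4203 genes (38.2%) had a range of at least 2 on that scale. A single cycle was sampled, so rhythmic here means a smooth course over this day. Recurrence could be looked at only between −11 and 13 h. The highest sample of a rhythmic gene lay in early night for 1990 genes (24.5%), in late day for 1852 (22.8%), in mid night for 674 and in late night for 597, windows of 3 libraries each. The first hour of light held it for 1728 genes (21.3%) and the morning for 1288 (15.8%), with 2 libraries each. The single sample at 0.5 h held the maximum of 1428 genes and that at 13 h the maximum of 1337. At −11 h, the same hour of the cycle as 13 h, lay the maximum of 181 genes. These 2 libraries were within 2-fold for 97.3% of genes, so the count at 13 h can turn on small differences between them. The 0.5 h library had the highest nuclear FPKM sum, 493359, and these counts were not repeated under another scaling. Only 4 genes had their maximum at −1 h, the dark library with the lowest median log2 shift of nuclear genes (−0.197). The functional lists followed one another through the day. All 8 photoprotection genes were highest in the first hour of light (5 of 8 without 0.5 h). In the morning came 15 of 17 genes of chlorophyll and haem biosynthesis and 11 of 14 Calvin-Benson cycle genes, and in late day all 18 DNA replication genes and 16 of 23 mitosis and cell-cycle regulators. Of 270 cilia genes, 141 were highest in early night, 69 in mid night and 36 in late night, and 12 of 15 fermentation genes were highest in early night.

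**Figure D1:**
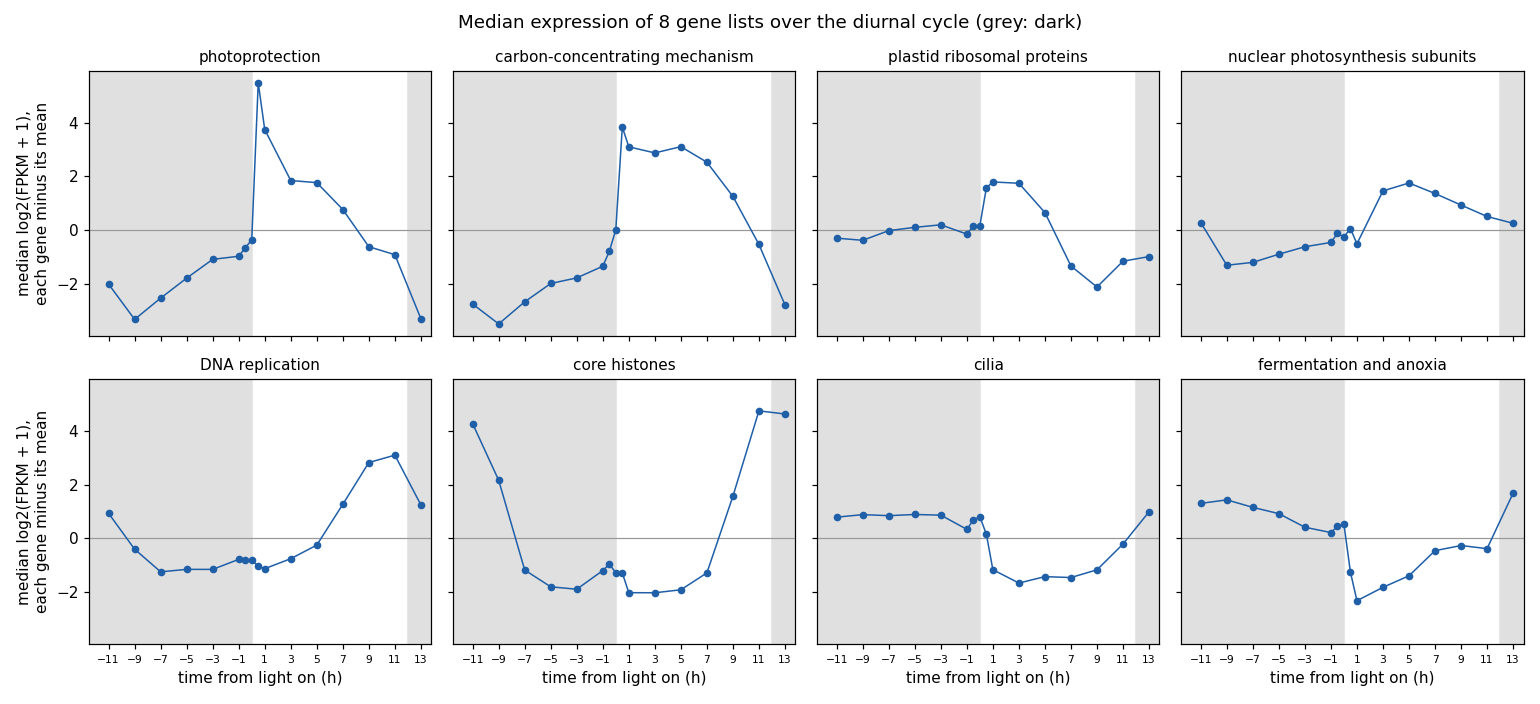
Median level of 8 gene lists at each of the 16 times, as log2(FPKM + 1) of each gene minus its mean over the times; the horizontal axis is the time from light on in hours, and grey marks darkness. Photoprotection and carbon-concentrating mechanism genes are high from the first light sample, DNA replication genes are highest in late day, and fermentation genes are low from 0.5 h and cilia genes from 1 h.

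**Figure D2:**
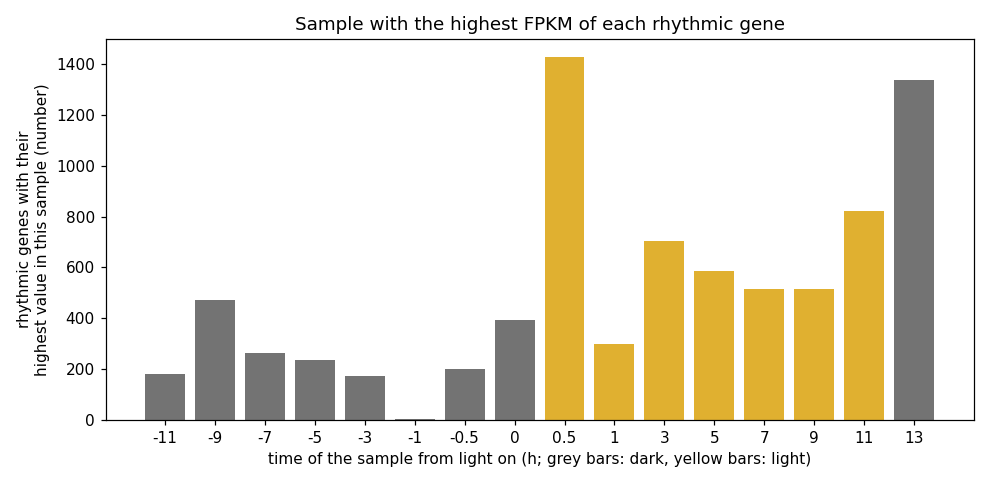
Number of rhythmic genes whose highest FPKM fell in each sample (vertical axis), by time from light on in hours (horizontal axis), with grey bars for dark and yellow bars for light samples. The tallest bars are 1428 genes at 0.5 h and 1337 genes at 13 h. The bar at −11 h, the same hour of the cycle as 13 h, holds 181 genes.

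Comparing the 7 light with the 9 dark samples asked which transcripts mark the lit and the unlit part of the cycle, with temperature changing together with light. Genes that concentrate inorganic carbon, dissipate excess light or make chlorophyll were higher in the light, and genes of cilia and of fermentation were higher in the dark. Of 16 measured genes of the carbon-concentrating mechanism, which raises CO2 around Rubisco, 14 rose in the light, with a median log2 change of 4.14 (camera adjusted p = 2.15e-05). With an estimated correlation between genes this list's adjusted p was 0.497, and no list of this comparison had a lower one. LCI1, an inorganic carbon transporter (Cre03.g162800.v5.5, chromosome 3, 2885264 to 2887871 in build v5.5, 7 exons), averaged 4.61 ± 4.96 FPKM (SD, n = 9) in the dark and 1382 ± 773 FPKM (n = 7) in the light. Its log2 change was 7.89 ± 0.60 (SE; limma adjusted p = 1.77e-07), and it was higher in all 7 light samples than in any of the 9 dark samples. CCP1 changed by 7.76 and the mitochondrial carbonic anhydrases CAH4 and CAH5 by 7.43 and 7.42, but these share 25.5 to 49.0% of their 50-base stretches with other genes and are uncertain one by one. All 8 photoprotection genes rose (median 3.16, camera adjusted p = 0.000713), among them LHCSR2 and LHCSR3 at 5.86 and 5.94, which share 45.5 and 45.8% of their stretches with other genes and are uncertain.

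Chlorophyll and haem biosynthesis rose in 14 of 17 members (median 1.81, camera adjusted p = 0.000861), for instance CRD1, the oxidative cyclase, by 2.84 ± 0.40. Its adjusted p with an estimated correlation was 0.497, as for the lists of heat shock chaperones and metal sentinels. Heat shock chaperones rose in 9 of 15 members (median 1.07, camera adjusted p = 0.00156). Among them HSP70C changed from 2.64 ± 3.11 FPKM in the dark to 44.1 ± 21.1 FPKM in the light (log2 change 3.87 ± 0.28, limma adjusted p = 1.06e-07), with all 7 light samples above the 9 dark ones, while CLPB1 fell. Of 13 sentinels of copper, iron and zinc limitation, 9 rose (median 1.60, camera adjusted p = 0.000979), including the copper-responsive cytochrome CYC6 at 4.53 ± 0.48 and the copper transporter CTR2 at 2.84. Within the dark, CYC6 read 5.49 FPKM at −11 h and 46.8 FPKM at 13 h.

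In the other direction, 228 of 270 cilia genes were lower in the light (median −1.86, camera adjusted p = 5.7e-26), among them FAP252 at −3.52 ± 0.41. For cilia and for the fermentation list the adjusted p was 0.497 with an estimated correlation. The 6 cilia genes that rose were FAP24, FAP280, FAP162, FAP224, FAP103 and FAP269. Fermentation and anoxia genes fell in 12 of 15 cases (median −2.05, camera adjusted p = 2.75e-05), and 1, the ferredoxin FDX5, rose by 3.90 ± 0.36. HYDA2, an iron hydrogenase (Cre09.g396600.v5.5, chromosome 9, 1740957 to 1745328, 10 exons), stood at 34.3 ± 6.65 FPKM (SD, n = 9) in the dark and 0.845 ± 0.435 FPKM (n = 7) in the light, a log2 change of −4.32 ± 0.13 (limma adjusted p = 2.72e-10), lower in all 7 light samples than in any dark one. Among the largest falls, PCK1, phosphoenolpyruvate carboxykinase, fell by 3.93, ICL1, isocitrate lyase of the glyoxylate cycle, by 3.85, and TAL1, transaldolase, by 3.69. The channelrhodopsin COP3 fell by 3.64 ± 0.20 and the plant-type cryptochrome CPH1 by 2.09, both without overlap of light and dark samples. They were the 2 photoreceptors measured in the list named for clock and photoreceptors, whose other members, RHP1 and RHP2, are Rhesus-type channel proteins. The single measured gamete marker, GSP1, rose by 1.36 ± 0.10. In the list of daughter-cell release and cell wall 13 of 27 genes fell, for instance the pherophorin PHC5 by 3.25, and 1, the septin SEP1, rose by 4.64. The list's camera adjusted p of 0.0472 became 0.596 with an estimated correlation, 0.123 with equal nuclear sums, 0.0668 with quantile normalization and 0.0518 with a pseudocount of 0.1 FPKM. Without −9, −0.5, 0, 1, 5 or 9 h it was 0.0547, 0.0526, 0.055, 0.0716, 0.0593 and 0.0542, so the camera call does not hold. The list median in these 6 fits stayed between −0.71 and −0.62, against −0.69 with all libraries, and fry called the list (adjusted p = 0.00346).

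Other photosynthesis lists changed less. Antenna genes rose in 17 of 21 cases (median 1.55, camera adjusted p = 0.000566), nuclear photosystem, cytochrome b6f and ATP synthase subunits in 19 of 25 (1.26, 6.7e-06) and Calvin-Benson cycle genes in 10 of 14 (1.27, 0.00116). Their adjusted p with an estimated correlation was 0.593, 0.497 and 0.497, and it was at least 0.497 for the called lists that follow. With equal nuclear sums, which lowered the median of all genes to −0.35, 11, 4 and 4 of them rose. Their medians were then 1.05, 0.76 and 0.77. Relative to that shift, the latter 2 were 1.11 and 1.12. With quantile normalization 12, 7 and 6 rose, and the Calvin-Benson adjusted p was 0.0609. Among the 34 rows of chloroplast-encoded photosynthesis genes, psbK, psbJ and psbN rose, and the list median of 0.58 (6.7e-06) became −0.03 with quantile normalization. Cytosolic ribosomal proteins had a median of 0.38 (7.39e-06) and became −0.12 with equal nuclear sums (0.23 relative to the shift, adjusted p = 0.715) or quantile normalization, although 1 of 69 members, RPS27e2, was called, at −1.60. Plastid ribosomal proteins had a median of 0.54 (0.00271), with an adjusted p of 0.507 under quantile normalization. Starch genes (median −0.08, adjusted p = 0.122), mitochondrial respiratory chain genes (0.08, 0.122), whose median turned to −0.44 with equal nuclear sums (−0.09 relative to the shift) and −0.12 with quantile normalization, and nitrogen, sulfur and phosphorus sentinels (0.66, 0.0878) were not called by camera. Without −11 h the nutrient sentinels were called (4 of 10 rose, adjusted p = 0.033). The self-contained test fry called the starch list (adjusted p = 0.000152), in which 1 gene rose and 5 fell, and the nutrient sentinels (0.000297). Without a minimum size, 3933 of 11000 genes were higher in this comparison and 3732 lower. These fry calls therefore do not set the lists apart from other genes. Within starch metabolism AMA1, an alpha-amylase, fell by 2.59 ± 0.18 in all 7 light samples.

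By limma, 1595 genes were higher in the light and 1530 lower, 3125 (28.4%) of 11000, with a median SE of 0.138. Counts adjusted over the list alone equalled these list counts in every case. Under equal nuclear sums the split became 901 higher and 2495 lower, and relative to the shift of all genes the medians of the carbon-concentrating, photoprotection and cilia lists were 4.16, 3.22 and −1.86.

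**Figure D3:**
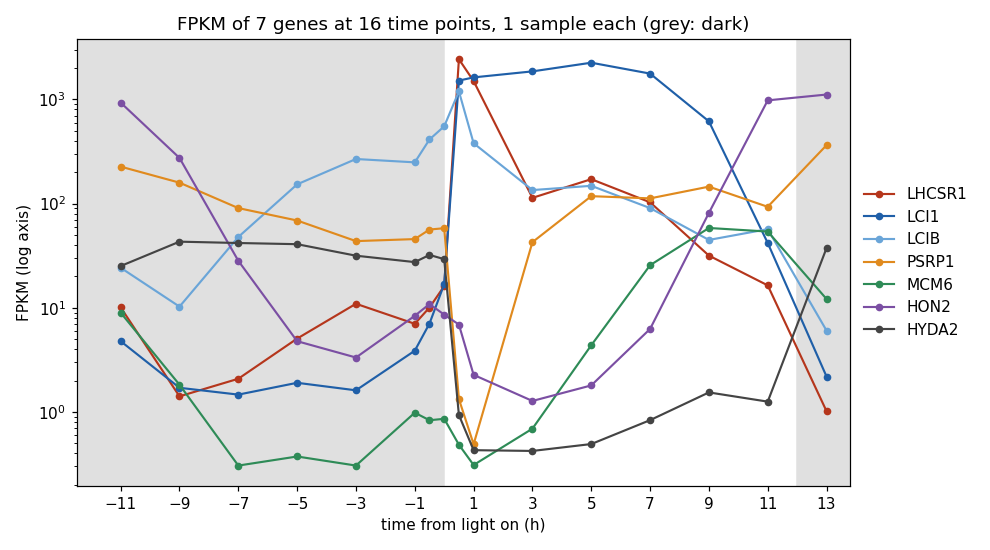
FPKM of LHCSR1, LCI1, LCIB, PSRP1, MCM6, HON2 and HYDA2 at each of the 16 times (logarithmic vertical axis), by time from light on in hours, with darkness in grey. PSRP1 drops to 0.910 FPKM on average in the first hour of light from 53.3 FPKM in late night, and HYDA2 is high only in the dark.

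The dawn comparison asked what changed between the last hour of darkness and the first hour of light, when light and temperature rose together. Photoprotection and carbon-concentrating genes rose together with chaperones, nutrient-limitation sentinels and plastid ribosomal proteins, while fermentation genes and the plastid ribosome hibernation factor fell. Photoprotection rose in 7 of 8 members (median log2 change 4.79, camera adjusted p = 0.000298). With an estimated correlation its adjusted p was 0.543, and no list at dawn had a lower one. LHCSR1, a light-harvesting-like protein of energy dissipation (Cre08.g365900.v5.5, chromosome 8, 1710379 to 1712537, 4 exons), went from 11.1 ± 4.65 FPKM (SD, n = 3) in late night to 1965 ± 659 FPKM (n = 2) in the first hour, a log2 change of 7.38 ± 0.81 (limma adjusted p = 1.53e-05). Both light samples were above all 3 dark ones, though 9.7% of its stretches are shared. PSBS1 changed by 8.49 ± 0.72, with 35.6% shared. In the carbon-concentrating mechanism 10 of 16 genes rose (median 4.35, camera adjusted p = 0.000163), among them LCI1 by 7.47 ± 1.08.

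Chaperones rose in 11 of 15 cases at dawn (median 2.01, camera adjusted p = 0.000368). The adjusted p with an estimated correlation was 0.543 for them and for the nutrient sentinels, 0.559 for plastid and 0.641 for cytosolic ribosomal proteins. HSP70C rose by 4.97 ± 0.49 and the cytosolic HSP70A by 3.61 ± 0.60, whereas CLPB1 fell by 1.45. Of 10 nitrogen, sulfur and phosphorus sentinels 6 rose (median 1.86, camera adjusted p = 0.00782): the transporters PTB4 (26.2% of its stretches shared), SLT1, SLT2 and AMT4, the arylsulfatase ARS5 and the nitrite reductase NII1. AMT4, an ammonium transporter (Cre13.g569850.v5.5, chromosome 13, 1187847 to 1192671, 8 exons), rose by 3.05 ± 0.26 (limma adjusted p = 2.61e-06), from 0.799 ± 0.150 to 15.1 ± 8.78 FPKM, in both light samples. SLT2 was no longer called without −1 and 1 h (2.77, adjusted p = 0.0845). Of 35 plastid ribosomal protein genes, 31 rose (median 1.67, camera adjusted p = 2.47e-07), for instance PRPS16 by 1.97 ± 0.36; with quantile normalization 6 rose, with a median of 0.80. The 1 that fell was PSRP1, a factor that holds plastid ribosomes inactive (Cre05.g237450.v5.5, chromosome 5, 2817337 to 2820699, 10 exons). It dropped from 53.3 ± 6.73 to 0.910 ± 0.594 FPKM, a log2 change of −4.86 ± 0.45 (limma adjusted p = 4.24e-06), in both light samples. Cytosolic ribosomal proteins had a median of 0.64 (camera adjusted p = 6.71e-09), which became 0.00 with quantile normalization, and 1 of 69 members, RPS27e2, fell.

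Falls at dawn included ICL1 at −5.12 ± 0.76, HYDA2 at −4.20 ± 0.24, TAL1 at −4.25 and COP3 at −4.01, each without overlap. Fermentation genes fell in 12 of 15 cases (median −2.44, camera adjusted p = 5.52e-06), and in 8 cases, with a median of −1.10, without 1 h; FDX5 rose by 3.82 ± 0.64. Under an estimated correlation the adjusted p was 0.543 for this list, for starch and for metal sentinels, and 0.641 for cilia. Starch genes fell in 8 of 20 cases (median −0.89, camera adjusted p = 0.0164) but lost the call without 1 h (5 fell, adjusted p = 0.0536). The amylase AMA1 fell by 2.70 ± 0.32 and the starch synthase SSS2 by 2.60 ± 0.40, while SSS1 rose by 1.41 ± 0.43. Among cilia genes 126 of 270 fell, or 133 when adjusted over the list alone (median −1.17, camera adjusted p = 8.28e-11). That number was 209 without 0.5 h, 35 without 1 h, 83 without 0 h and 45 without −1 and 1 h. Under equal nuclear sums it was 214, at a median of −1.19 relative to the shift of all genes, and with quantile normalization 174. FAP24, FAP103, FAP162, FAP224 and FAP280 rose; 10 cilia genes rose without 1 h and 1 with either scaling. Copper, iron and zinc sentinels rose in 5 of 13 cases (median 0.79, camera adjusted p = 0.0078), with CTR2 at 2.87 ± 0.36. The camera adjusted p was 0.0604 without 1 h, where 4 rose and the median was 0.89, and 0.131 among genes of at least 5 FPKM on average. Fry, which does not compare a list with other genes, called it (adjusted p = 0.00239).

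In all, 1837 genes rose at dawn and 1669 fell, 3506 (31.9%) of 11000 by limma, with a median SE of 0.247. The set of 1 h minus −1 h and the set of 0.5 h minus the mean of −0.5 and 0 h compare libraries of one kind. Across all 11000 genes Pearson's r between the sets was 0.885. In these sets photoprotection had medians of 4.39 and 5.31, the carbon-concentrating mechanism 4.34 and 4.51, chaperones 2.12 and 2.12, the nutrient sentinels 1.76 and 1.54, and metal sentinels 1.06 and 0.92. Plastid ribosomal proteins had medians of 1.94 and 1.44, cytosolic ones 0.56 and 0.77, fermentation −2.88 and −1.14, starch −0.89 and −0.54, and cilia −1.52 and −0.57. Except for cilia, counts adjusted over the list alone equalled those over all genes for these lists. With equal nuclear sums the median of all genes moved from −0.06 to −0.41 and 1042 genes rose and 2825 fell, while relative to that shift the photoprotection, carbon-concentrating and plastid ribosomal medians were 4.73, 4.35 and 1.54.

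The day comparison asked what changed between the first hour of light and late day, at constant light and temperature. DNA replication and cell-cycle genes rose, while genes for plastid ribosomal proteins, photoprotection and much of the carbon-concentrating mechanism fell. All 18 measured DNA replication genes rose (median log2 change 3.38, camera adjusted p = 2.87e-06). With an estimated correlation the adjusted p of this and every other list described for the day was 0.625, the smallest of the comparison. MCM6, a subunit of the replicative helicase (Cre03.g178650.v5.5, chromosome 3, 4802239 to 4808304, 14 exons), went from 0.398 ± 0.124 FPKM (SD, n = 2) to 45.9 ± 17.7 FPKM (n = 3), a log2 change of 4.99 ± 0.58 (limma adjusted p = 1.66e-05), and was higher in all 3 late-day samples. PCN1, the sliding clamp, rose by 5.10 ± 0.74. Of 23 mitosis and cell-cycle regulators 16 rose (median 1.84, camera adjusted p = 0.00164). The plastid division proteins FTSZ1 and MIND1 rose by 4.92 ± 0.72 and 5.23 ± 0.94. Core histones rose in 60 of 73 cases, 64 adjusted over the list alone (median 3.38, camera adjusted p = 7.43e-06), but in 24, 7, 38 and 26 cases without 0.5, 1, 9 or 11 h, and 72 of the 75 listed histone genes share at least 5% of their stretches.

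Plastid ribosomal proteins fell in 33 of 35 cases over the day (quartiles −3.41 and −2.96, camera adjusted p = 5.64e-14), for instance PRPS6 by 3.56 ± 0.38. Here the adjusted p with an estimated correlation was 0.625, and likewise for the next 3 lists. PSRP1 and PSRP4 rose, PSRP1 by 5.96 ± 0.45 (limma adjusted p = 1.82e-06) to 117 ± 26.5 FPKM, in all 3 late-day samples, and PSRP4 by 1.14 ± 0.21. The chloroplast-encoded rps19 (chloroplast, 24932 to 26112, 1 exon) fell by 4.11 ± 0.47. Cytosolic ribosomal proteins fell in 53 of 69 cases (median −1.08, camera adjusted p = 6.3e-17), in 10 without 0.5 h and 35 without 11 h. With equal nuclear sums 4 fell, at a median of −0.79, or −1.06 relative to the shift of all genes, and with quantile normalization 1 fell, at a median of −0.28. RPS27e2 went the other way, by 2.46 ± 0.36. Photoprotection fell in all 8 genes (median −3.48, camera adjusted p = 0.00044; 5 genes without 0.5 h), with ELI3, an early light-inducible protein, at −7.51 ± 0.81. In the carbon-concentrating mechanism 9 of 16 genes fell, 8 adjusted over the list alone (median −2.11, camera adjusted p = 0.00164). Without 0.5 h 5 fell, without 7 h 16 fell, and without 11 h the median was −1.05; the thylakoid carbonic anhydrase CAH3 fell by 3.70 ± 0.48. AMT4 fell back by 3.71 ± 0.26.

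Antenna genes rose in 20 of 21 cases over the day (median 2.38, camera adjusted p = 0.0013) and LHCB7 fell by 1.27; without 1 h 9 rose, with a median of 1.76. For this list and the next, the adjusted p was 0.625 with an estimated correlation. Mitochondrial respiratory chain genes rose in 22 of 76 cases and 1, ATP1B, fell (median 0.47, camera adjusted p = 0.00164), and without 1 h 16 rose and 5 fell. Among them were the ATP synthase subunits ATP2 at 2.27 ± 0.28 and ATP1A at 2.12 ± 0.29, each without overlap. The amylase AMA2 rose by 3.81 ± 0.35 and ADH1, the alcohol and aldehyde dehydrogenase of fermentation, by 3.40 ± 0.56.

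Over the day 2549 genes rose and 2012 fell, 4561 (41.5%) of 11000, the highest count of the window comparisons. Counts adjusted over the list alone were equal where not given. With equal nuclear sums the median of all genes moved from 0.07 to 0.27, 2957 genes rose and 1410 fell, and the medians of the replication and plastid ribosomal lists relative to that shift were 3.14 and −3.19. Without −1 and 1 h, 2138 genes rose and 2543 fell.

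At dusk the question was what changed between late day and early night, when light and temperature fall together. Of the early-night libraries only 13 h followed these late-day samples, while −11 and −9 h came from the night before. Differences between the 2 nights therefore enter this comparison. Chlorophyll and haem biosynthesis had a median log2 difference of −1.70 between −11 and 13 h, being lower at 13 h. A fit with 13 h alone leaves 1 library in early night, so its calls are not given. Cilia and fermentation genes and 12 of 27 genes of daughter-cell release and cell wall rose, and genes of carbon concentration, chlorophyll synthesis and DNA replication fell. Of 270 cilia genes 219 rose, 221 adjusted over the list alone (median log2 change 1.85, camera adjusted p = 9.76e-25). With an estimated correlation the adjusted p of this and every other called list described for dusk was 0.598, the smallest of the comparison. FAP71, a flagella-associated protein (Cre06.g261900.v5.5, chromosome 6, 1744794 to 1748079, 8 exons), went from 3.51 ± 5.15 FPKM (SD, n = 3) to 45.4 ± 5.40 FPKM (n = 3), a log2 change of 3.99 ± 0.55 (limma adjusted p = 8.85e-05), and was higher in all 3 early-night samples. FAP252 rose by 4.01 ± 0.66, while FAP24, FAP36 and FAP269 fell. Of 15 fermentation genes 10 rose (median 1.99, camera adjusted p = 8.6e-05), with HYDA2 at 4.01 ± 0.21, and 1, FDX5, fell by 2.52 ± 0.58.

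In the list of daughter-cell release and cell wall 12 of 27 genes rose at dusk (median 0.63, camera adjusted p = 0.00366; adjusted p = 0.598 with an estimated correlation). PHC15, a pherophorin of the extracellular matrix family (Cre09.g396100.v5.5, chromosome 9, 1809519 to 1811468, 4 exons), went from 93.4 ± 93.1 to 1469 ± 182 FPKM, by 4.45 ± 0.85 on the log2 scale (limma adjusted p = 0.000783), higher in all 3 early-night samples. PHC22 rose by 4.55 ± 0.90, and the 1 gene of this list that fell was SEP1, by 3.88 ± 0.49.

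Carbon-concentrating genes fell in 14 of 16 cases at dusk (median −3.40, camera adjusted p = 8.6e-05), with LCI1 at −6.61 ± 0.96 and NAR1.2, a chloroplast envelope bicarbonate channel, at −5.96 ± 0.88. The adjusted p with an estimated correlation was 0.598 for this list and for chlorophyll synthesis, DNA replication and photoprotection. Chlorophyll and haem biosynthesis fell in 15 of 17 cases (median −2.04, camera adjusted p = 0.000386), for instance CTH1, a cyclase, by 2.99 ± 0.53. DNA replication fell in 15 of 18 cases (median −1.80, camera adjusted p = 0.000141), with the helicase subunit MCM2 at −2.35 ± 0.35, and MAT3, the retinoblastoma-related size regulator, fell by 2.75 ± 0.36, while the aurora-like kinase ALK3 rose by 3.65 ± 0.62. Photoprotection fell in 5 of 8 cases, 6 adjusted over the list alone (median −2.07, camera adjusted p = 0.0088): ELI1 and ELI4, and LHCSR1, LHCSR2 and LHCSR3, which share stretches and are uncertain one by one. The photoreceptors COP3 and CPH1 rose, CPH1 by 2.57 ± 0.26 and COP3 from 6.99 ± 1.67 to 71.7 ± 6.27 FPKM. Starch genes were not called by camera (5 rose, 3 fell, adjusted p = 0.29) but were by fry (adjusted p = 0.015), which does not compare a list with other genes.

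By limma 1625 genes rose at dusk and 1709 fell, 3334 (30.3%) of 11000, with a median SE of 0.221. With equal nuclear sums the median of all genes moved from 0.03 to 0.14, and relative to that shift the cilia and carbon-concentrating medians were 1.80 and −3.43. Counts adjusted over the list alone were equal where not given.

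The night comparison asked what changed between early and late night, in constant darkness and at constant temperature. Most core histone genes and 23 of 76 respiratory chain genes fell, and 5 of 8 photoprotection and 7 of 16 carbon-concentrating genes rose before the light came on. Core histones fell in 65 of 73 cases (median log2 change −4.96, camera adjusted p = 3.56e-11), although reads shared among copies leave single histone genes uncertain. With an estimated correlation the adjusted p of this and every other called list described for the night was 0.784, the smallest of the comparison. HON2, a linker histone with no shared stretch (Cre06.g275900.v5.5, chromosome 6, 3192345 to 3193790, 3 exons), went from 773 ± 441 FPKM (SD, n = 3) to 9.28 ± 1.37 FPKM (n = 3), a log2 change of −6.01 (limma adjusted p = 0.00289), lower in all 3 late-night samples. The cyclin CYCA1 fell by 4.67 ± 0.95. Mitochondrial respiratory chain genes fell in 23 of 76 cases (median −0.74, camera adjusted p = 2.66e-08), among them the ATP synthase subunits ASA7 and ASA9 by 1.71 ± 0.23 and 1.67 ± 0.23; with quantile normalization 6 fell, 1 rose and the median was −0.22.

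Photoprotection rose over the night in 5 of 8 cases (median 2.26, camera adjusted p = 0.00197): ELI3 by 5.79 ± 0.72, and ELI2, ELI4, LHCSR2 and LHCSR3, the last 2 uncertain one by one for their shared stretches. The adjusted p with an estimated correlation was 0.784 here and for the carbon-concentrating and chlorophyll lists. Carbon-concentrating genes rose in 7 of 16 cases (median 1.28, camera adjusted p = 0.000442; median 0.74 without 0 h). LCIB, a protein that recaptures CO2 in the chloroplast (Cre10.g452800.v5.5, chromosome 10, 4608866 to 4611901, 6 exons), rose from 13.5 ± 9.52 to 404 ± 152 FPKM, by 4.93 ± 0.63 (limma adjusted p = 0.00016), in all 3 late-night samples. Its partner LCIC rose by 5.98 ± 0.67 and the Rubisco linker LCI5 by 5.38 ± 0.80, and RCA1, Rubisco activase, rose by 3.98 ± 0.61. Chlorophyll and haem biosynthesis rose in 12 of 17 cases (median 1.92, camera adjusted p = 0.00032), in 5 without −9 h, 6 without 13 h and 6 without 0 h, and its fry adjusted p was 0.0542; 1 member, GTR1, fell by 1.01 ± 0.20, but was not called without −9 or 13 h or with any other scaling tried. The pherophorins PHC22 and PHC15 fell by 4.76 ± 0.90 and 4.29 ± 0.85, within a cell wall list in which 7 of 27 genes rose and 11 fell and which was not called (camera adjusted p = 0.953). AMA2 fell by 3.05 ± 0.31 and the acetate kinase ACK1 by 2.34 ± 0.37.

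Over the night 847 genes rose and 1648 fell, 2495 (22.7%) of 11000, with a median SE of 0.221; with quantile normalization 1309 rose and 1190 fell, and without −1 and 1 h 967 rose and 1385 fell. Counts adjusted over the list alone were equal for these lists.

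The libraries at −11 and 13 h asked how far the pattern returned a day later. Their log2 values differed with an SD of 0.425 across genes, and 97.3% of genes lay within 2-fold. Across genes, which are not independent replicates, Pearson's r was 0.975, against 0.997 for −0.5 and 0 h, the closest pair, whose differences had an SD of 0.139. Chlorophyll and haem biosynthesis had the largest median difference of the lists, −1.70 on the log2 scale, with 11 of its 17 genes at least 2-fold lower at 13 h, against 227 lower and 68 higher among all 11000 genes. At least 2-fold lower were also 6 of 15 heat shock chaperones, 4 of 10 nutrient sentinels, 4 of 14 Calvin-Benson cycle genes and 4 of 16 carbon-concentrating genes. GSA1, which makes aminolevulinate, stood at 27.1 FPKM at −11 h and 1.98 FPKM at 13 h. Among genes with a symbol and a mean of at least 5 FPKM, LHCBM9 fell most, from 163.73 to 3.92 FPKM. In the same set CYC6 rose most, from 5.49 to 46.83 FPKM. With 1 library on each side, these differences have no replicate check.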

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

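The test of deeper sequencing alone was written after the low numbers of zeros had been seen, and the share among genes above 0 in each library compared was added after the other values. Of 32 checks for a single library far from the others of its phase, 4 picked out a library, all at −1 h or 1 h. Chance flags about 1 in 20 groups. The 4 concerned the median shift of nuclear genes and the summed FPKM of low genes. The low genes were chosen for being low away from dawn, so this chance rate does not hold for their sum. The number of genes listed at 0 was checked too, and that check picked out neither library.

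The median shift of the nuclear genes was −0.197 at −1 h, the lowest of the 9 dark samples, and −0.246 at 1 h, the lowest of the 7 light samples. The summed FPKM of 1571 genes that lie under 0.05 FPKM on average in the samples away from dawn was 102.18 at −1 h and 92.11 at 1 h, the highest of their phases. Both libraries listed few genes at 0. Deeper sequencing alone would leave these sums near those of −0.5, 0 and 0.5 h, which were 25.26, 25.35 and 37.63. The sums were 2.72 and 2.45 times the highest of these, so it is excluded. Reads from the opposite strand of overlapping genes remain open: the excess was 2.7 times that of isolated genes, but with 3 overlapping genes against 641 its 95% bootstrap interval ran from 0.59 to 6.5. A low background of reads over most genes fits without being established: 85.1% of the low genes were higher at 1 h than at 0.5 h and 91.0% at −1 h than on average at −0.5 and 0 h, shares that fewer zeros raise by themselves, and among low genes above 0 in each library compared they were 80.4% and 91.4%. No biological explanation was tested.

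Chance as the source of the counts was tested by splitting the same samples otherwise. The real order of the times was 1 of 100 orders and gave 8129 rhythmic genes against 1770 in the highest other order, and the real light and dark grouping was 1 of 100 random assignments to windows with 3125 genes against 1435. Random order and random assignment can be excluded, but both also part neighbouring times, which resemble each other, so they do not single out light against dark from other groupings of neighbouring times. For dusk the real split was 1 of 10 with 3334 genes against 600. For night it was 1 of 10 with 2495 genes against 0 by limma. In these last 2 cases the splits are too few for a share under 0.05. The other splits also mix samples of both windows and part neighbouring times. A difference between the windows then counts as error, so low counts in them say little about chance.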

How the results depend on the processing

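Of the alternatives here, leaving out −1 and 1 h together was added after the files had been seen. Restricting the test to genes of at least 5 FPKM on average gave 3772 rhythmic genes, 1759 in light against dark, 1795 at dawn, 2305 over the day, 1725 at dusk and 1530 over the night. Fewer genes were tested there, and whether that alone accounts for the lower counts was not tested. Asking for no minimum change gave 7665, 5940, 6891, 6101 and 4917 genes in the 5 comparisons, as the requirement on size was dropped. With an estimated correlation 0 lists by camera passed in each comparison, against 15, 11, 14, 15 and 9. The estimates ran from 0.092 for nutrient sentinels to 0.903 for cytosolic ribosomal proteins, with 0.696 for cilia, against the preset 0.01. Camera p-values at the preset therefore assume far less correlation between genes than was estimated, and small ones are not strong support. Fry called 4 lists for night, and the cause was not tested. Among lists called by camera, the median changed sign in light against dark for cytosolic ribosomal proteins and chloroplast-encoded genes. The former had −0.12 with equal nuclear sums, 0.23 above the median of all genes, and −0.12 with quantile normalization. The latter had −0.03 with quantile normalization. Under that normalization the former became 0.00 at dawn and the latter 0.00 over the day, and the cause was not tested. Equal nuclear sums did not lower all genes alike, since 1 FPKM was added before the logarithm. In light against dark the cytosolic ribosomal median moved from 0.38 to −0.12 and the DNA replication median from 0.77 to 0.63. Medians relative to the shift of all genes are therefore approximate. Leaving out 1 library gave 7845 to 8275 rhythmic genes, 3004 to 3439 in light against dark, 3308 to 3616 at dawn, 3965 to 4833 over the day, 2972 to 4105 at dusk and 1997 to 2876 over the night. Lists called ran from 13 to 16, 9 to 11, 13 to 15, 13 to 15 and 8 to 11 in these comparisons, and 19 to 22 of 22 lists kept their peak window. Without −1 and 1 h there were 7909 rhythmic genes, and 3105, 3210, 4681, 3306 and 2352 genes in the comparisons. For named genes 4902 of 4963 alternative values kept their call, 61 were weaker and 0 turned. This share overstates stability, since named genes were chosen for large changes and some alternatives could hardly alter a call. Asking for no minimum change could lose none of 190, and mid-night libraries enter the change only in light against dark. For lists 2427 of 2590 kept their call, 123 were weaker, 35 stronger and 5 turned. Sequencing depth is not given in the sources used here. No paired analysis was possible because each time has 1 library.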

Other observations

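The plastid classes and the genes high at 0.5 h were picked after their values had been seen, and the tests of neighbouring genes were fixed before their results.

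Members of each class of chloroplast-encoded genes fell over the day, and no difference between classes was tested. All 18 plastid-encoded ribosomal protein genes, such as rps19, fell by limma between the first hour of light and late day, with a median log2 change of −3.19, and 15 rose at dusk, with a median of 1.58. The 5 genes of the plastid-encoded RNA polymerase, rpoA, rpoB1, rpoB2, rpoC1 and rpoC2, all rose at dusk (median 1.75), and 4 did so without 7 h. Over the day these 5 fell (median −1.62), but 2 did without 0.5 h, 2 without 1 h, 2 without 7 h and 2 with quantile normalization. Among 18 rows of other plastid genes 12 fell over the day (median −1.58) and 7 rose at dusk. Of 34 rows of plastid-encoded photosynthesis genes, 12 fell over the day, with a median of −0.48 that became 0.00 with quantile normalization.

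At 0.5 h 16 genes stood at least 4-fold above both neighbouring samples, 0 h and 1 h, and 10 of them at least 4-fold above every other sample. The 1 h library stands apart from the rest, and 15 genes were at least 4-fold below both neighbours in it. PSBS1, a photosystem II subunit of energy dissipation, read 0.243, 1731 and 121 FPKM at 0, 0.5 and 1 h, though it shares 35.6% of its stretches, and LCI7 read 7.28, 412 and 83.4 FPKM. Each of these times has 1 library, so no replicate error can be given.

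Adjacent nuclear genes had weakly correlated time profiles, above all in divergent pairs: Pearson's r averaged 0.123 over 7347 pairs, against at most 0.032 in 100 rotations of the gene order, so chance placement is excluded. Paralogs sharing reads are excluded as the only source, since pairs with under 5% shared stretches still averaged 0.096 over 5766 pairs, against at most 0.037 in rotations. Divergent pairs averaged 0.235 over 2230 pairs, tandem pairs 0.085 over 3105 and convergent pairs 0.058 over 2012, and among pairs with little shared sequence 0.203, 0.047 and 0.047. Divergent and tandem pairs differed by 0.15 (95% bootstrap interval 0.121 to 0.18; permutation p = 0.0001, the smallest that 10000 permutations can give). A shared promoter region of divergent genes is a hypothesis that could account for this part of the pattern, found and tested on the same data.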
